A study of Mus musculus with 6 samples.

How the data were processed

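RNA was measured in 6 mouse heart samples, 2 in each of 3 groups: Myh6 RH/+ with vehicle, Myh6 RH/RQ with vehicle and Myh6 RH/RQ with AAV-hpCas13d. Per the labels, tissue was taken 12 months after administration to newborns, and mRNA was captured on poly-T beads from 1 µg of total RNA. The groups were read from the sample labels. HISAT2, HTSeq, DESeq2 and the mm10 build are named by the submitters' processing notes; versions, the role of each tool, strandedness and the annotation were not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be separated.

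The authors deposited 3 full tables, each with 4 libraries, whose expression values are CPM, gene counts scaled to the total of the library. The same deposited tables hold, per the file headers, a mean signal per gene (counts divided by DESeq2 size factors and averaged over the table), a log2 fold change with its standard error, a test score and p-values with and without adjustment. A library that stood in 2 tables had the same CPM in both, with a largest difference of 0. The authors' deposited shorter lists hold the genes with an adjusted p under 0.05 and more than a 1.5-fold change. Every sample column was matched to a sample, with 0 left over. Each CPM value was a whole multiple of the value of 1 read in its library (100% of values, tolerance 0.001), so whole reads were recovered. Library totals were 38091444 and 39914862 reads for RH/+ vehicle, 51017058 and 38792351 for RH/RQ vehicle, and 36269261 and 37927494 for treated RH/RQ hearts. A count of 3 reads, the limit that 0 reads allow, was 0.0788 and 0.0752, 0.0588 and 0.0773, and 0.0827 and 0.0791 CPM in that order. Genes of the mitochondrial genome took between 17.2% and 22.4% of the reads, and the top gene, mt.Co1, between 8.29% and 10.7%. The 2 libraries of a group differed by more than sampling noise, with a mean chi-square per gene of 11.7, 16.1 and 22.6 over 18733 genes in the 3 groups, so none was counted as a duplicate. The first 2 principal components held 38.1% and 27% of the variance.

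The plan written before the data were examined fixed the groups, comparisons, gene lists, naming rule and most alternatives. It foresaw edgeR on raw counts and, for normalised values with recoverable reads, limma with the count tests as alternatives. Because the deposited unit is CPM, the reported test was limma with a trend on log2(CPM + 1), scaled by library total only; a fold change on this scale understates the change of low genes. All 6 libraries entered 1 fit of 3 group means, since 2 libraries per group leave little to estimate a spread from. Genes were kept by filterByExpr with a minimum count of 10, which left 16804 of the 29385 genes in the tables. Benjamini-Hochberg adjustment was over all genes tested, with calls at an adjusted p under 0.05. The comparisons were RH/RQ vehicle against RH/+ vehicle, treated against vehicle RH/RQ, and treated RH/RQ against RH/+ vehicle. On the recovered reads edgeR called 918, 381 and 411 genes in these comparisons and DESeq2 906, 363 and 418; the edgeR common biological coefficient of variation was 0.0974. DESeq2 run on the 4 libraries of each table gave the authors' deposited log2 fold changes within 1e-06 for 100% of genes.

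The 29 lists held 705 genes, of which 13 were not found by symbol. Each was tested, two-sided, with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists within a comparison. The naming rule took, for each comparison, Myh6 and Myh7, the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and a symbol that is not a predicted gene, and the 3 members of each described list with the smallest p. Sex-linked genes were to be described through their list. Genes named outside this rule, including those that make up counts of 5 or fewer on a list, were chosen after their values were seen. Some genes that the rule or a count would name are not reported here. Coordinates are those of GENCODE M21 on GRCm38 (mm10), in which 28969 symbols had 1 match and 40 had several. Because comparisons share libraries, the overlap of calls and the covariance of fold changes were set beside simulated unchanged groups and beside independent lists.

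The alternatives were edgeR, DESeq2, RLE factors, 2 other filters on low genes, the 4 libraries of a comparison alone, a replicate block, a test against a fold of 1.5, pseudocounts of 0.1 and 5, and leaving out each library. TMM factors, leaving out genes on X and Y, and CPM over nuclear genes were added after the data were seen. Each test was run on simulated reads drawn from the libraries' means and totals with 200 genes changed. The changed genes were taken from those with a mean of at least 1 CPM, so recovery of lower genes was not measured. At simulated folds of 1.5, 2 and 4, limma recovered 57.5%, 87.3% and 96.9% of the changed genes for RH/RQ vehicle against RH/+, 49.1%, 88.9% and 100% for treated against vehicle RH/RQ, and 60.9%, 87.3% and 98.6% for treated RH/RQ against RH/+, on 16804 genes each. Of the limma calls on these simulated reads 3.05%, 5.17% and 5.68% were false in that order of comparisons. In the last comparison 9.78% of the edgeR calls and 5.81% of the DESeq2 calls were false. The software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.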

Results

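Poly(A) RNA from 6 mouse heart samples was sequenced 12 months after an administration given to newborns. Myh6 encodes the alpha myosin heavy chain, the main motor protein of the adult mouse ventricle. All 6 samples carried altered Myh6 alleles, which the labels name RH and RQ without spelling them out. The samples form 3 groups of 2: Myh6 RH/+ with vehicle, Myh6 RH/RQ with vehicle, and Myh6 RH/RQ with AAV-hpCas13d, an adeno-associated virus carrying a form of Cas13d. Cas13d is an enzyme that cuts RNA at sites set by a guide RNA. The files gave CPM, gene counts scaled to the library total, and the reads recovered from them numbered between 36269261 and 51017058 per library. A gene with 0 reads was limited by 3 counts to at most 0.0588 to 0.0827 CPM, depending on the library. Such floors cover counting error only. The labels do not say whether the samples of a group came from separate animals, so p-values measure only the spread between these samples.

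Sex-linked transcripts separated the groups, and their single levels are given here after their values were seen. Xist, the RNA that silences an X chromosome in females, was at 272 ± 10.3 CPM in RH/+ vehicle hearts, at 0.163 ± 0.158 CPM in RH/RQ vehicle hearts and at 312 ± 19.3 CPM in treated RH/RQ hearts (SD, n = 2 each). The Y-linked gene Ddx3y had 0 reads in the 4 libraries of the RH/+ and treated groups and 85.2 ± 0.0114 CPM in the RH/RQ vehicle group (SD, n = 2), at least 1030-fold higher by the highest floor of a single library. Eif2s3y (66.9 CPM), Uty (22.7 CPM) and Kdm5d (20.6 CPM) were likewise present in the RH/RQ vehicle libraries and had at most 1 read in either other group. Kdm6a, an X-linked gene chosen after its values were seen, was lower in the RH/RQ vehicle hearts at 18.2 ± 0.902 CPM against 33.6 ± 1.97 CPM in RH/+ (SD, n = 2 each; limma adjusted p = 4.2e-05). The labels give no sex. By these transcripts the RH/RQ vehicle libraries had a male pattern and the other 4 libraries a female pattern. Genotype and treatment therefore cannot be told apart from sex in the 2 comparisons that involve the RH/RQ vehicle group. In the 2 comparisons that involve the RH/RQ vehicle group, the sex-linked pattern changed with the group, and between treated RH/RQ and RH/+ hearts it did not: there limma called 0 of the 5 listed sex-linked genes, 0 passed an unadjusted p of 0.05, and edgeR and DESeq2 called 0.

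**Figure D1:**
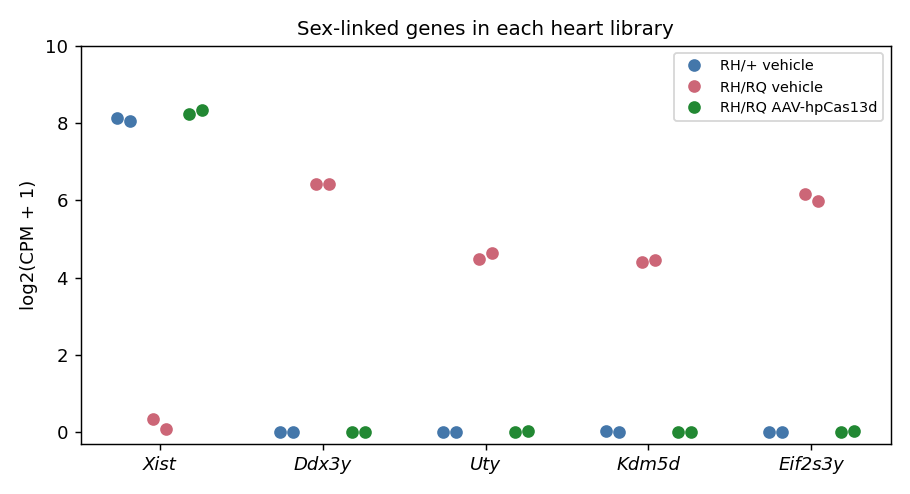
Levels of 5 sex-linked genes as log2(CPM + 1), with 1 point per heart library and 3 groups of 2 libraries. Xist is near 0 in both RH/RQ vehicle libraries only, and the 4 Y-linked genes are above 4 on this scale in those libraries and near 0 in the other 4.

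Total Myh6 RNA (chromosome 14, 54941921 to 54966927 on the minus strand, GRCm38) did not pass the test in any comparison. Its level was 14786 and 18251 CPM in the RH/+ libraries, 15066 and 17720 CPM in the RH/RQ vehicle libraries, and 14297 and 15258 CPM in the treated libraries. The log2 fold change was -0.01 (SE 0.22) for RH/RQ vehicle against RH/+, with a limma adjusted p of 0.993, and -0.15 (SE 0.22) for treated against vehicle RH/RQ, with a limma adjusted p of 0.852. Gene-level values do not separate the Myh6 alleles, so they do not show how the RNA of each allele changed. Myh7, the beta myosin heavy chain of the fetal ventricle (chromosome 14, 54970684 to 54994626, minus strand), was at 270 ± 21.7 CPM in RH/+, 588 ± 104 CPM in RH/RQ vehicle and 534 ± 40.5 CPM in treated hearts (SD, n = 2 each). It rose in RH/RQ vehicle hearts by 1.11 (SE 0.11) on the log2 scale (limma adjusted p = 6.85e-07) and stood 0.98 (SE 0.11) above RH/+ in treated hearts (limma adjusted p = 1.25e-05). Between treated and vehicle RH/RQ hearts its log2 fold change was -0.13 (SE 0.11), which did not pass (limma adjusted p = 0.698). Myh6 and Myh7 share long stretches of sequence, so reads counted for either gene are uncertain to that extent.

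**Figure D2:**
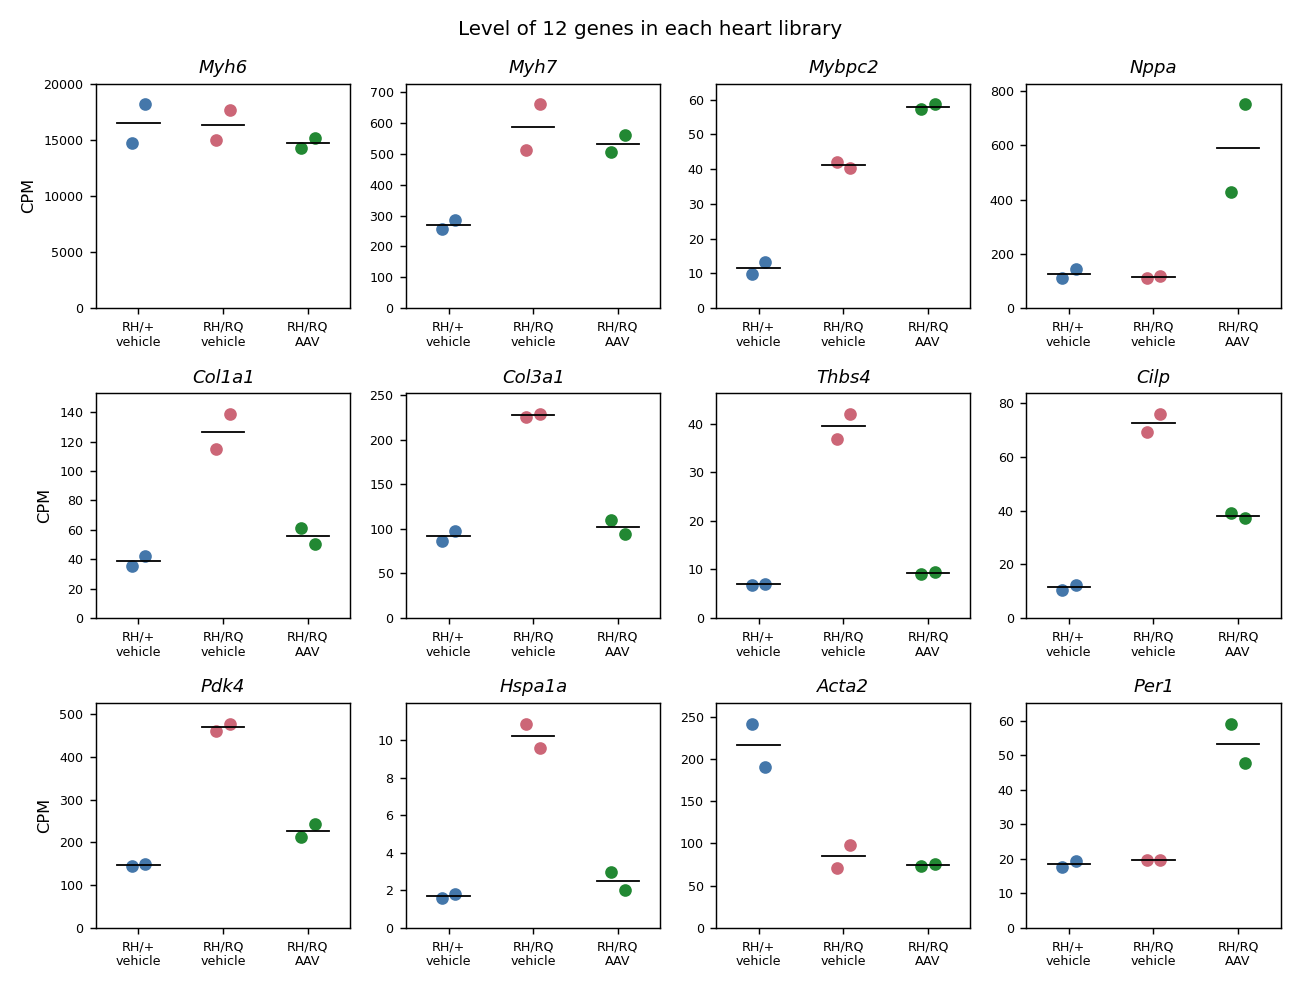
CPM of 12 genes in each heart library, with 1 point per library and a line at the mean of each group of 2; every axis starts at 0. Myh6 overlaps between groups, Myh7 is higher in both RH/RQ groups, Col1a1, Col3a1, Thbs4, Pdk4 and Hspa1a are highest in RH/RQ vehicle hearts, and Nppa and Per1 are highest in treated hearts.

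RH/RQ vehicle hearts were compared with RH/+ vehicle hearts, which have the wild-type allele in place of the RQ allele. The groups also differed in the sex-linked pattern, so the comparison cannot separate genotype from sex. Many genes of the extracellular matrix rose. Cilp, a secreted matrix protein (chromosome 9, 65265180 to 65280605), rose from 11.4 ± 1.15 to 72.8 ± 4.69 CPM, a log2 fold change of 2.57 (SE 0.11; limma adjusted p = 1.18e-13). Thbs4, a thrombospondin (chromosome 13, 92751590 to 92794818), rose from 6.92 ± 0.17 to 39.5 ± 3.60 CPM. Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042), rose from 38.9 ± 4.82 to 127 ± 17.0 CPM (SD, n = 2 each). Of the 53 tested genes on the matrix and fibrosis list, 44 rose, 0 fell and 9 did not pass; adjusted over the list alone, 47 rose and 1 fell. The median log2 fold change of the list was 0.88. The list test (camera) gave an adjusted p of 1.62e-65, and the adjusted p was 0.114 with an estimated correlation. In this comparison Y-linked transcripts were present in the RH/RQ group, apart from 1 read of Kdm5d in RH/+.

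The other large rises included further secreted proteins. C7, a complement component, rose from 4.38 ± 1.07 to 27.3 ± 0.596 CPM, and Ltbp2, a binding protein of latent TGF-beta, from 2.48 ± 0.317 to 15.7 ± 4.54 CPM (SD, n = 2 each). Edn3 (log2 fold change 2.17), Serpina3n (2.09), Srpx (1.93) and Timp1 (1.89) also rose; Serpina3n belongs to a family of near-identical genes, which makes its count less certain. Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose from 147 ± 2.07 to 469 ± 12.5 CPM (SD, n = 2 each), a log2 fold change of 1.66 (SE 0.09; limma adjusted p = 2.64e-11). It was on the fatty acid oxidation list, of whose 39 genes 3 rose (Pdk4, Ucp3 and Angptl4) and 4 fell, among them Ppargc1a, Ech1 and Dgat2 (4 and 5 adjusted over the list alone). That list did not pass (camera adjusted p = 0.0756). Of its 4 falls 1 was left without RH/+ replicate 2 and 0 without RH/+ replicate 1 or either RH/RQ vehicle library, while DESeq2 called 10 falls. These rises went with the presence of Y-linked transcripts.

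Genes of the fetal and hypertrophy list rose in RH/RQ vehicle hearts. Of its 18 tested genes 8 rose and 0 fell, or 11 and 0 adjusted over the list alone (camera adjusted p = 2.89e-11; adjusted p = 0.1 with an estimated correlation). Besides Myh7 they included Mybpc2, the myosin-binding protein C of fast skeletal muscle, at 11.6 ± 2.32 CPM in RH/+ and 41.2 ± 1.09 CPM in RH/RQ, and Rcan1, an inhibitor of calcineurin, with a log2 fold change of 0.81. Acta1, skeletal actin, rose from 591 ± 84.0 to 1235 ± 199 CPM, and Myot, a Z-disc protein, from 98.8 ± 0.892 to 191 ± 7.70 CPM (SD, n = 2 each). Nppa, the precursor of atrial natriuretic peptide, was at 126 ± 23.0 and 114 ± 3.79 CPM and was not called. The RH/RQ libraries that showed these rises were also those with Y-linked transcripts.

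Several lists of other cell types and of stress genes rose in RH/RQ vehicle hearts, whose sex-linked transcripts also differed from RH/+. Of 20 fibroblast markers 10 rose and 0 fell (12 and 1 adjusted over the list alone), with a camera adjusted p of 1.52e-10 and an adjusted p of 0.363 with an estimated correlation; 6 of these markers are also matrix genes. Without RH/RQ vehicle replicate 1, 6 markers rose. Of 36 macrophage and monocyte genes 9 rose and 0 fell (18 and 0 adjusted over the list alone), among them Cx3cr1 with a log2 fold change of 1.28 and Csf1r with 0.56; the camera adjusted p was 1.9e-08, and the adjusted p was 0.363 with an estimated correlation. That count was 5 without RH/+ replicate 1 and 3 without RH/RQ vehicle replicate 1. Of 24 immediate early genes 9 rose and 0 fell (14 and 0 adjusted over the list alone), with Jun at 45.4 ± 0.602 and 94.7 ± 4.10 CPM and Egr2 at 0.873 ± 0.101 and 4.22 ± 0.275 CPM (SD, n = 2 each). The immediate early list had a camera adjusted p of 1.52e-10 and an adjusted p of 0.363 with an estimated correlation. Of 34 heat shock and unfolded protein genes 7 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.00378; adjusted p = 0.363 with an estimated correlation). These were led by Hspa1a, from 1.68 ± 0.144 to 10.2 ± 0.912 CPM, and Hspa1b, from 3.82 ± 0.688 to 16.6 ± 2.47 CPM (SD, n = 2 each), near-identical genes of inducible HSP70 between which reads cannot be divided with certainty.

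Among the genes lower in RH/RQ vehicle hearts, Cyp26b1, an enzyme that degrades retinoic acid, fell from 5.91 ± 0.594 to 1.18 ± 0.103 CPM, Acta2, smooth muscle actin, from 216 ± 36.2 to 84.7 ± 18.8 CPM, and Mylk4, a myosin light chain kinase, from 201 ± 13.6 to 81.4 ± 1.85 CPM (SD, n = 2 each). Sv2c, Lepr, Sorcs2, Scn10a, Epn3 and Eps8l1 fell with log2 fold changes between -1.46 and -1.15. Car3, the adipocyte and muscle carbonic anhydrase, fell by 1.85, and by 0.76 without RH/+ replicate 2, the library with 7.34 CPM of Car3 against 0.866 CPM in RH/+ replicate 1. Of 44 interferon response genes 7 fell and Rsad2 rose (15 and 1 adjusted over the list alone; camera adjusted p = 1.41e-10; adjusted p = 0.363 with an estimated correlation), led by Usp18 with a log2 fold change of -0.89; 1 fall was left without RH/+ replicate 1 or without RH/RQ vehicle replicate 2, and the rise of Rsad2 was not called once any of the 4 libraries was left out, nor with edgeR or DESeq2. On that list edgeR called 12 falls, and DESeq2 11, as did limma with TMM or RLE factors. Of 30 potassium and sodium channel and connexin genes Kcnip2, Kcne1, Scn4b, Gja3 and Hcn2 fell and Kcnc1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 4.11e-05; adjusted p = 0.114 with an estimated correlation). Those 5 falls became 1 without RH/+ replicate 1, 1 without RH/RQ vehicle replicate 1, 3 without RH/RQ vehicle replicate 2 and 8 without either treated library, with edgeR, with DESeq2 or with TMM or RLE factors, and Kcnc1 was not called without RH/+ replicate 2 or RH/RQ vehicle replicate 2. Of 55 nuclear genes of the respiratory chain Ndufa5 and Cox7a1 fell and 0 rose (6 and 0 adjusted over the list alone; edgeR called 6 lower, DESeq2 25 and limma 7 with TMM or RLE factors), while the median log2 fold change was -0.24 and none of the 55 was above 0 (camera adjusted p = 1.95e-20; adjusted p = 0.363 with an estimated correlation). Both single-gene falls on that list were lost without any of the 4 libraries compared, and 11 and 10 genes fell without treated replicate 1 or 2. The RH/RQ libraries with these lower levels also lacked Xist.

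In all, 838 of 16804 tested genes differed between RH/RQ vehicle and RH/+ vehicle hearts by limma on log2(CPM + 1) at an adjusted p under 0.05, 585 of them higher and 253 lower, with 30 on X and 6 on Y. On the recovered reads edgeR called 524 higher and 394 lower and DESeq2 452 and 454, and limma called 527 and 404 with TMM factors, 513 and 407 with RLE factors and 823 and 249 on CPM over nuclear genes, so the excess of rises depended on the scaling. The count was 343 without RH/+ replicate 1, 523 without RH/+ replicate 2, 471 without RH/RQ vehicle replicate 1, 427 without RH/RQ vehicle replicate 2, 57 with no filter on low genes and 48 when tested against a fold of 1.5. Of the 29 gene lists 13 passed camera with the preset correlation and 0 passed with an estimated one, where 4 had an unadjusted p under 0.05; 5 passed fry.

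Treated and vehicle RH/RQ hearts share the genotype but differ in AAV-hpCas13d and in the sex-linked pattern. Their comparison cannot separate treatment from sex. Many matrix genes fell. Thbs4 fell from 39.5 ± 3.60 to 9.27 ± 0.241 CPM, a log2 fold change of -1.98 (SE 0.13; limma adjusted p = 1.5e-09). Col3a1, the chain of type III collagen (chromosome 1, 45311538 to 45349706), fell from 227 ± 2.22 to 102 ± 11.3 CPM, and Col1a1 from 127 ± 17.0 to 55.9 ± 7.85 CPM (SD, n = 2 each). Of the 53 matrix and fibrosis genes 25 fell, Ccn2 and Col14a1 rose and 26 did not pass; adjusted over the list alone, 31 fell and 2 rose. The median log2 fold change was -0.45 (camera adjusted p = 1.62e-32; adjusted p = 0.275 with an estimated correlation). The number of falls was 15 without RH/RQ vehicle replicate 1 and 12 without RH/RQ vehicle replicate 2. In this comparison the treated libraries had Xist and at most 1 read of each listed Y-linked gene, while the RH/RQ vehicle libraries had the male pattern.

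Other falls were those of C7, from 27.3 ± 0.596 to 3.40 ± 2.05 CPM, Fmod, a collagen-binding proteoglycan, with a log2 fold change of -1.88, Lox, which cross-links collagen, with -1.33, and Ccl11, an eosinophil chemokine, with -1.45. Pdk4 fell from 469 ± 12.5 to 228 ± 21.5 CPM (SD, n = 2 each). Eps8l1, already lower in RH/RQ than in RH/+ hearts, fell further, from 5.66 ± 1.23 to 0.742 ± 0.0425 CPM (SD, n = 2 each). Of the 34 heat shock and unfolded protein genes 8 fell and Herpud1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 1.12e-12; adjusted p = 0.102 with an estimated correlation). Hspa1a reached 2.50 ± 0.67 CPM and Hspa1b 4.48 ± 1.11 CPM (SD, n = 2 each), and Hsph1 had a log2 fold change of -0.70. The call of Herpud1 was lost without RH/RQ vehicle replicate 1, RH/RQ vehicle replicate 2 or treated replicate 1. With edgeR, TMM factors, RLE factors or CPM over nuclear genes 8 genes of the list fell and 0 rose. These falls, too, were seen between groups that differed in the sex-linked pattern.

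Few single genes of the fibroblast and macrophage lists were called with treatment. Of 20 fibroblast markers 3 fell and 0 rose, or 3 and 4 adjusted over the list alone; the 3 were the collagen genes Col1a1, Col1a2 and Col3a1, which are also on the matrix list. The fibroblast list did not pass (camera adjusted p = 0.385): its median log2 fold change was 0.11, its mean was -0.05 and the test pointed down. Of 36 macrophage and monocyte genes the chemokines Ccl2, Ccl7 and Ccl8 fell and 0 rose (5 and 0 adjusted over the list alone; 5 falls with edgeR, TMM factors, RLE factors or CPM over nuclear genes). The macrophage list as a whole pointed down, with a median log2 fold change of -0.149 and 5 of its 36 genes above 0. Its camera adjusted p was 2.54e-07, and the adjusted p was 0.338 with an estimated correlation. Ccl2 lost its call without RH/RQ vehicle replicate 1 or treated replicate 1 (limma adjusted p up to 0.0952). Ccl8 lost it without either RH/RQ vehicle library or treated replicate 2 (up to 0.178) and with DESeq2, and Ccl7 without RH/RQ vehicle replicate 1 or either treated library (up to 0.367). Xist and the Y-linked genes differed between these groups as above.

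Outside the sex-linked genes, the named genes with the largest rises with treatment were Cyp26b1 and Nppa (chromosome 4, 148000722 to 148002079). Nppa was at 428 and 753 CPM in the treated libraries against 112 and 117 CPM in the RH/RQ vehicle libraries, a log2 fold change of 2.30 (SE 0.16; limma adjusted p = 2.11e-09). Cyp26b1 rose from 1.18 ± 0.103 to 10.5 ± 0.598 CPM (SD, n = 2 each). Per1, a clock gene, rose from 19.7 ± 0.0952 to 53.4 ± 8.11 CPM, Ddit4, an inhibitor of mTORC1, from 56.7 ± 2.66 to 145 ± 28.9 CPM, and Depp1 from 17.6 ± 3.01 to 49.2 ± 13.6 CPM (SD, n = 2 each). Arrdc2 (log2 fold change 1.45), S100a9 (1.30), Grin2c (1.22), Usp18 (1.17) and Fam107a (1.15) rose as well. Of 19 clock genes 5 rose, among them Per1, Per2, Per3 and Nr1d2, and 0 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.000689; adjusted p = 0.275 with an estimated correlation); Per2 had a log2 fold change of 0.76 and Per3 of 0.71. The number of rises was 3 without RH/RQ vehicle replicate 1 or without RH/RQ vehicle replicate 2, and with edgeR, TMM factors, RLE factors or CPM over nuclear genes 3 rose and 1 fell. Between RH/RQ vehicle and RH/+ hearts 2 clock genes were higher, among them Arntl, and 3 lower, among them Per3 and Nr1d2 (4 and 7 adjusted over the list alone; camera adjusted p = 0.117). There 1 was higher when any 1 of the 4 libraries was left out, and 1 was lower without RH/+ replicate 2, 0 without RH/RQ vehicle replicate 2 and 5 without either treated library, while edgeR and DESeq2 called 1 higher and 5 lower. The sex-linked pattern differed between the groups of both comparisons.

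Between treated and vehicle RH/RQ hearts, whose sex-linked transcripts also differed, 344 of 16804 genes differed by the same limma test, 205 higher and 139 lower, with 16 of them on X and 5 on Y. Here the split depended on the scaling and on single libraries: edgeR gave 181 higher and 200 lower, DESeq2 176 and 187, limma 172 and 196 with TMM factors, 173 and 195 with RLE factors, and 164 and 202 on CPM over nuclear genes. The count was 134 without RH/RQ vehicle replicate 2 (62 higher and 72 lower), 225 without treated replicate 1 (101 and 124), 613 without treated replicate 2 (473 and 140), 15 with no filter on low genes and 24 when tested against a fold of 1.5. Of the 29 lists 16 passed camera with the preset correlation and 0 with an estimated one, where 3 had an unadjusted p under 0.05; 1 passed fry.

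**Figure D3:**
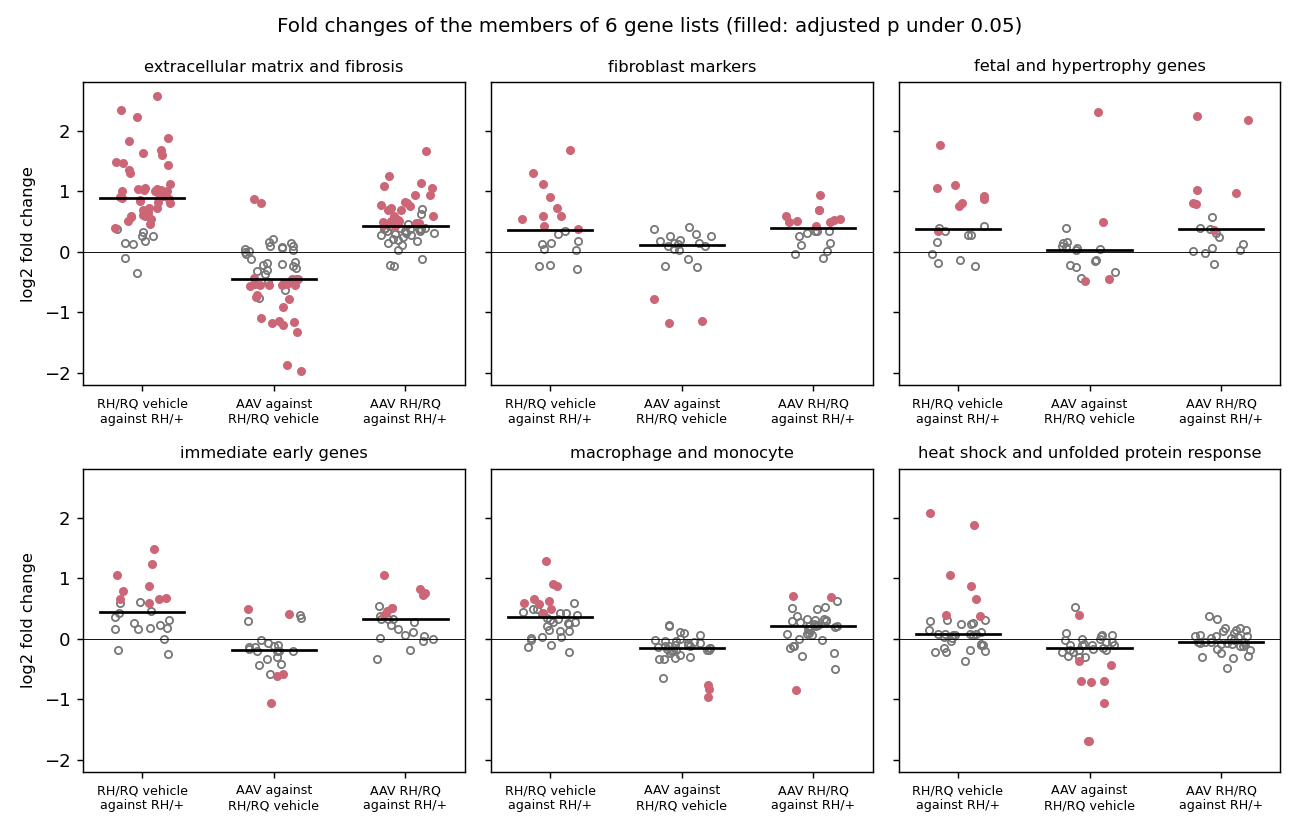
Log2 fold changes of the members of 6 gene lists in the 3 comparisons; each circle is a gene, filled where its limma adjusted p was under 0.05, and the line is the list's median. The matrix list has medians of 0.88, -0.45 and 0.43 from left to right, and the heat shock list has called genes in the first 2 comparisons and 0 in the third.

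The genes called between the genotypes and those called with treatment overlapped in opposite directions. Of the 838 genotype calls 160 (19.1%) were called with treatment in the opposite direction, 95 that rose in RH/RQ and then fell and 65 that fell and then rose. Independent lists of the same sizes would share 4.84 and 3.09 genes. Both comparisons use the RH/RQ vehicle libraries, which tends to give opposite signs with no effect at all. The 20 simulated sets of unchanged groups gave 0 shared calls, which sets no reference, since unchanged groups give few calls to share. Part of the excess may come from the shared libraries, which are too few to be split. The RH/RQ vehicle group alone also had the male pattern, so a gene that differs by sex would move in opposite directions. With X and Y genes left out 146 such calls remained, but this does not remove effects of sex on other chromosomes. The simulated sets held no effect of sex, so the excess cannot be read as reversal by treatment. The covariance of the fold changes across genes was -0.0421 against -0.0111 in 100 simulated sets, a difference of -0.031; with the X and Y genes left out it was -0.031, a difference of -0.0198. The Pearson correlation across genes, which are not independent replicates, was -0.647, and -0.578 with the X and Y genes left out, against -0.5 simulated. On the matrix list 25 of the 44 genes that rose in RH/RQ hearts fell with treatment, and on the heat shock list 7 of 7 did. The 160 included the 5 listed sex-linked genes, and the number was 74 without RH/RQ vehicle replicate 2, 12 with no filter on low genes and 15 when both tests were against a fold of 1.5.

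**Figure D4:**
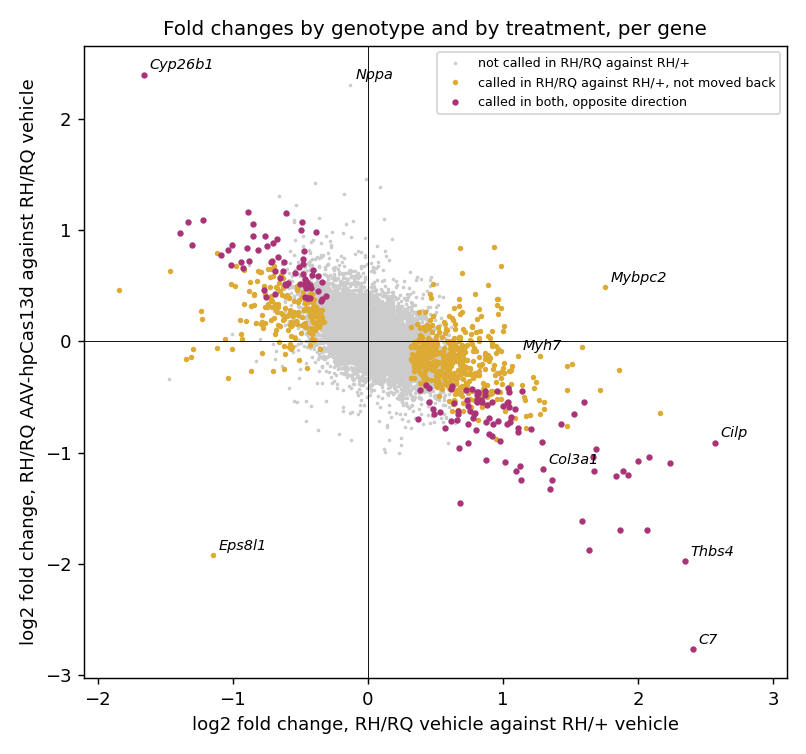
Log2 fold change of each tested gene for RH/RQ vehicle against RH/+ vehicle (horizontal) and for RH/RQ AAV-hpCas13d against RH/RQ vehicle (vertical), without the 5 listed sex-linked genes. Genes called in both comparisons with opposite signs lie at the lower right (Thbs4, C7, Cilp, Col3a1) and at the upper left (Cyp26b1), while Eps8l1 lies at the lower left and Mybpc2 at the upper right.

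Treated RH/RQ hearts were also set against RH/+ vehicle hearts. These groups differ in both genotype and AAV-hpCas13d, so a difference between them cannot be assigned to either alone. The 5 listed sex-linked genes did not separate these groups, although 20 other genes on X and 1 on Y were called. Many matrix genes stood above the RH/+ level. Cilp was at 38.2 ± 1.57 CPM against 11.4 ± 1.15 CPM (SD, n = 2 each), a log2 fold change of 1.66 (SE 0.11; limma adjusted p = 2.36e-09), whereas Thbs4 was at 9.27 ± 0.241 against 6.92 ± 0.17 CPM. Ccn2, a secreted matricellular growth factor, was at 76.7 ± 13.2 CPM against 39.2 ± 0.407 CPM in RH/+ and 43.0 ± 1.37 CPM in RH/RQ vehicle hearts (SD, n = 2 each). Of the 53 matrix and fibrosis genes 24 were higher than in RH/+ and 0 lower, or 43 and 1 adjusted over the list alone (median log2 fold change 0.43; camera adjusted p = 7.99e-30; adjusted p = 0.232 with an estimated correlation). That number was 12 without RH/+ replicate 1. The number higher than in RH/+ was 19 with edgeR and 20 with DESeq2, which called 1 lower. With TMM factors, RLE factors or CPM over nuclear genes it was between 16 and 24. Of the 44 matrix genes that were higher in RH/RQ vehicle hearts than in RH/+, 22 were also called higher than RH/+ in treated hearts.

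Genes of the fetal and hypertrophy list were also called above RH/+. Of its 18 genes 7 were higher and 0 lower, or 12 and 0 adjusted over the list alone. The camera adjusted p was 2.62e-11, and the adjusted p was 0.196 with an estimated correlation. Of the 8 genes that were higher in RH/RQ vehicle hearts than in RH/+, 5 were called here. Mybpc2 reached 58.1 ± 1.00 CPM, the largest rise over RH/+ with a log2 fold change of 2.24, and Nppa followed with 2.17. Neb, the giant thin-filament protein nebulin (log2 fold change 1.78), and the transcription factors Tbx15 (1.66) and Vgll2 (1.60) were higher as well, as were Fetub (1.54), Resf1 (1.52), Edn3 (1.52) and Per1 (1.47). Of 30 sarcomere genes Myh7, Myom2, Myh7b, Synpo2l and Myot were higher and 0 lower, or 5 and 0 adjusted over the list alone, and 3 were higher without RH/+ replicate 1; the list did not pass (camera adjusted p = 0.0508). Of 29 p53 and cell death genes Cdkn1a, Phlda3 and Bcl2l1 were higher and 0 lower (6 and 0 adjusted over the list alone; camera adjusted p = 0.0154; adjusted p = 0.463 with an estimated correlation). Cdkn1a, an inhibitor of cell division, was at 42.4 ± 0.586 CPM against 20.9 ± 2.06 CPM in RH/+ (SD, n = 2 each). Phlda3 (limma adjusted p = 0.0444) lost its call without either RH/+ library or treated replicate 1 (up to 0.341), with edgeR or DESeq2, with TMM or RLE factors, on CPM over nuclear genes and with a pseudocount of 5.

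Among fibroblast markers 10 of 20 were higher than in RH/+ and 0 lower (15 and 0 adjusted over the list alone; camera adjusted p = 1.47e-11; adjusted p = 0.329 with an estimated correlation), with Dcn, decorin, at 875 ± 102 CPM against 541 ± 21.1 CPM and Pi16 at 110 ± 6.79 against 68.2 ± 6.59 CPM (SD, n = 2 each). The number was 4 without RH/+ replicate 1 or without treated replicate 1, 5 with edgeR, 8 with DESeq2 and 6 with TMM or RLE factors. Of 24 immediate early genes 8 were higher and 0 lower (10 and 1 adjusted over the list alone; camera adjusted p = 4.73e-05; adjusted p = 0.463 with an estimated correlation); 4 were left without RH/+ replicate 1, 3 without RH/+ replicate 2 and 2 without treated replicate 1. Of the 34 heat shock genes limma called 0, with 5 at an unadjusted p under 0.05, 0 adjusted over the list alone, 4 lower by edgeR and 3 lower by DESeq2. That list had a median log2 fold change of -0.05 (camera adjusted p = 0.000719; adjusted p = 0.232 with an estimated correlation).

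Lower than in RH/+ were Eps8l1, Acta2 and Mylk4, each of which was also lower in vehicle RH/RQ hearts. Eps8l1 had a log2 fold change of -3.07. Acta2 was at 74.8 ± 1.92 CPM against 216 ± 36.2 CPM, and Mylk4 at 77.5 ± 3.95 CPM against 201 ± 13.6 CPM (SD, n = 2 each). Rtn4r, Aqp4 and Pfkfb1 were lower with log2 fold changes between -1.18 and -1.08. Car3, Msln and Kcne1 were called lower too, but Car3 lost its call without RH/+ replicate 2 or either treated library (limma adjusted p up to 0.632) and with DESeq2 or a pseudocount of 0.1 or 5, Msln without RH/+ replicate 1 or treated replicate 2 (up to 0.317) and with DESeq2 or a pseudocount of 5, and Kcne1 without RH/+ replicate 1 or treated replicate 1 (up to 0.211). Of 30 potassium and sodium channel and connexin genes Kcnj2, Kcnj3, Kcne1 and Scn4b were lower and Kcna5 and Kcnc1 higher (7 and 2 adjusted over the list alone; camera adjusted p = 5.36e-05; adjusted p = 0.232 with an estimated correlation). Scn4b, a sodium channel subunit, was at 60.0 ± 10.2 CPM against 99.6 ± 10.3 CPM, and Kcna5, a potassium channel, was higher at 36.5 ± 4.79 against 19.2 ± 0.198 CPM (SD, n = 2 each). The 4 falls were 1 without RH/+ replicate 1 or treated replicate 1 and 2 without RH/+ replicate 2.

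Between treated RH/RQ and RH/+ hearts 480 of 16804 genes differed by limma, 391 higher and 89 lower, with 20 of them on X and 1 on Y. The split was 248 and 163 with edgeR, 229 and 189 with DESeq2, and, with limma, 237 and 164 with TMM factors, 235 and 164 with RLE factors and 368 and 109 on CPM over nuclear genes. The count was 172 without RH/+ replicate 1, 277 without treated replicate 1, 7 with no filter on low genes and 19 when tested against a fold of 1.5. Of the 838 genotype calls 239 (28.5%) were also called here in the same direction, 199 higher and 40 lower, where independent lists would share 13.6 and 1.34; both comparisons use the RH/+ libraries. The covariance of these fold changes was 0.032 against 0.0111 simulated, a difference of 0.0209. Of the 29 lists 17 passed camera with the preset correlation and 0 with an estimated one, where 6 had an unadjusted p under 0.05; 1 passed fry.

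The authors' deposited tables, made with 4 libraries each, give an adjusted p under 0.05 for 1036 genes for genotype, 265 for treatment and 347 for treated RH/RQ against RH/+. The authors' deposited lists, which also ask for more than a 1.5-fold change, hold 427, 185 and 194 genes. Limma called 699, 233 and 256 of the genes with an adjusted p under 0.05 in the authors' deposited tables, each in the same direction as there, and 410, 173 and 187 of those on the authors' deposited lists.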

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

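The TMM factors, the omission of X and Y genes and CPM over nuclear genes were chosen after the data were seen. Scaling by library size only is the reported setting. For RH/RQ vehicle against RH/+, treated against vehicle RH/RQ and treated RH/RQ against RH/+ in this order, the counts of changed genes were 918, 381 and 411 with edgeR, 906, 363 and 418 with DESeq2, 920, 368 and 399 with RLE factors, 931, 368 and 401 with TMM factors, 1072, 366 and 477 with CPM over nuclear genes, 820, 343 and 504 with a mean of at least 1 CPM, 1158, 347 and 489 in fits of 4 libraries, 840, 335 and 487 with a pseudocount of 0.1, and 781, 290 and 391 with a pseudocount of 5. Of the calls reported, edgeR kept 754, 295 and 333 and DESeq2 688, 287 and 304. Without a filter on low genes the counts were 57, 15 and 7, the genotype calls with an opposite call in treated hearts (moved back) 12 and the covariance of fold changes -0.0245; the cause was not tested. Against a fold of 1.5 they were 48, 24 and 19 with 15 moved back, as a stricter threshold makes them fewer. With X and Y genes left out the covariance was -0.031. Leaving out 1 library gave 343 to 1156, 134 to 613 and 172 to 703 genes, 74 to 215 moved back and a covariance of -0.0578 to -0.0414; the lone library left in a group is assumed to vary like those of the other groups. Between libraries with the same first digit in the sample title, correlations of deviations were 0.13, -0.02 and 0.074. Such low values show little pairing across genes but cannot exclude a shared batch. With that digit as a replicate block 1173, 567 and 715 genes were called, against 838, 344 and 480 without it, and 264 moved back. Across named genes 1513 results without 1 library kept their side of the threshold, 187 lost a call, 58 gained one and 0 changed sign as a call. Of the list tests 46 lost their call with an estimated correlation and 39 with fry. The erythroid list, RH/RQ vehicle against RH/+, changed direction and passed without RH/RQ vehicle replicate 1 (camera adjusted p = 0.0301; 0.681 with all libraries, 0.00318 to 0.702 without 1). The mitochondrially encoded list has no value on CPM over nuclear genes. Depth limits what can be said of genes under 0.0827 CPM.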

Other observations

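The tests of sex, fibroblast content, atrial tissue, time of day and glucocorticoid signalling were chosen after the results were seen. The 29 gene lists were planned, but the list of glucocorticoid-responsive genes was added after the results were seen. Haemoglobin transcripts were lower in treated hearts, with Hba.a1 at 99.0 ± 23.9 CPM in RH/+, 114 ± 46.4 CPM in RH/RQ vehicle and 58.4 ± 0.568 CPM in treated hearts (SD, n = 2 each). Against RH/+ hearts, which share the sex-linked pattern, limma called 4 of 7 erythroid genes lower and 0 higher, and DESeq2 called 1 lower. Fewer were called by limma without RH/+ replicate 2 or without either treated library. The median log2 fold change there was -0.631, with a camera adjusted p of 7.39e-09 and an adjusted p of 0.232 with an estimated correlation. Of 7 erythroid genes Hba.a1, Hbb.bs and Hbb.bt fell against vehicle RH/RQ hearts (0 higher and 5 lower adjusted over the list alone; camera adjusted p = 2.54e-07; adjusted p = 0.275 with an estimated correlation). The 3 falls were 0 without RH/RQ vehicle replicate 2 and 1 without treated replicate 2, DESeq2 called 1, and near-identical globin genes share reads. Of 13 mitochondrially encoded genes mt.Co3 and mt.Nd4l fell with treatment (0 and 4 adjusted over the list alone; camera adjusted p = 2.54e-07; adjusted p = 0.275 with an estimated correlation), mt.Co3 from 1606 ± 18.3 to 881 ± 7.69 CPM (SD, n = 2 each). The call of mt.Nd4l (limma adjusted p = 0.0299) ended without RH/RQ vehicle replicate 1 or either treated library (adjusted p up to 0.364) and with a pseudocount of 5. Of 7 neutrophil genes S100a8 and S100a9 rose with treatment (3 and 0 adjusted over the list alone), and 1 was left without either RH/RQ vehicle library or treated replicate 1. The neutrophil list had a camera adjusted p of 0.00721, of 0.143 without treated replicate 1, and an adjusted p of 0.518 with an estimated correlation. Of 12 epicardial and mesothelial markers Muc16 fell, from 2.04 ± 1.45 to 0.434 ± 0.166 CPM (SD, n = 2 each; 0 and 4 adjusted over the list alone; camera adjusted p = 5.06e-06; adjusted p = 0.275 with an estimated correlation). That count was 3 without RH/RQ vehicle replicate 1 and 0 without RH/RQ vehicle replicate 2 or either treated library. Of 10 atrial markers Nppa and Kcna5 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.00891; adjusted p = 0.275 with an estimated correlation), and the camera adjusted p was 0.181 without RH/RQ vehicle replicate 1 and 0.0592 without treated replicate 2. The sex-linked transcripts also differed between these groups.

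Between RH/RQ vehicle and RH/+ hearts, where the sex-linked transcripts differed too, Mki67, Top2a and Ccnb2 of 29 cell cycle genes rose (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00356; adjusted p = 0.407 with an estimated correlation). Mki67, a marker of dividing cells, went from 1.68 ± 0.597 to 4.90 ± 0.0304 CPM, and Top2a from 1.09 ± 0.0909 to 3.34 ± 0.679 CPM (SD, n = 2 each). Ccnb2 (limma adjusted p = 0.0334) was not called without RH/+ replicate 2 or either RH/RQ vehicle library (adjusted p up to 0.291), by edgeR or DESeq2, which each called 2 genes of the list higher, or with a pseudocount of 0.1. Of 27 glycolysis and glucose uptake genes Pfkp rose and Eno3 and Pdk2 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.000724; adjusted p = 0.524 with an estimated correlation). Those 2 falls were 0 without either RH/+ library or RH/RQ vehicle replicate 1, 1 without RH/RQ vehicle replicate 2, 4 without either treated library, 4 with DESeq2 and 1 on CPM over nuclear genes. The camera adjusted p of that list was 0.0971 without RH/+ replicate 2 and 0.251 without RH/RQ vehicle replicate 1. Of 28 lymphocyte genes limma called 0, with 4 at an unadjusted p under 0.05, 0 adjusted over the list alone and 0 by edgeR or DESeq2. The lymphocyte list had a median log2 fold change of -0.17 (camera adjusted p = 0.0167; adjusted p = 0.688 with an estimated correlation), and its camera adjusted p was 0.258 without RH/+ replicate 1, 0.0503 without RH/RQ vehicle replicate 2, 0.0623 with TMM and 0.0666 with RLE factors. Of 11 adipocyte markers Plin1, Cfd and Car3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.139), and 1 was left without RH/+ replicate 2 or either RH/RQ vehicle library; Cfd was at 0.236 CPM in RH/+ replicate 1 and 4.11 CPM in replicate 2.

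The other lists did not pass camera in that comparison. Of 23 endothelial markers Aqp1, a water channel, fell from 407 ± 23.1 to 263 ± 27.6 CPM (SD, n = 2 each; 0 and 1 adjusted over the list alone; camera adjusted p = 0.419). Of 17 smooth muscle and pericyte markers Acta2 and Abcc9 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.675), 1 of them without either RH/+ library or RH/RQ vehicle replicate 2. Of 26 calcium handling genes Casq1 and Camk2b rose and Cacnb2 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.496). The 2 rises were 1 without RH/+ replicate 1 or RH/RQ vehicle replicate 1, and Cacnb2 was not called once any of the 4 libraries was left out; DESeq2 called 3 lower. Of 9 skeletal muscle markers Casq1 and Acta1 rose and Myl1 and Tnnt1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.419), the falls being 1 without RH/+ replicate 1 or RH/RQ vehicle replicate 2 and 0 without RH/+ replicate 2 or RH/RQ vehicle replicate 1. Of 23 natriuretic, adrenergic and renin-angiotensin genes Ace, Ednrb and Prkg1 rose (4 and 2 adjusted over the list alone; camera adjusted p = 0.437), 1 of them without RH/+ replicate 1 or either RH/RQ vehicle library. Ace, which makes angiotensin II, went from 43.9 ± 4.79 to 73.2 ± 2.47 CPM (SD, n = 2 each). Of 11 Schwann cell and neuronal markers limma called 0, with 3 at an unadjusted p under 0.05, 1 and 1 adjusted over the list alone, and 0 by edgeR or DESeq2 (camera adjusted p = 0.371). Ccl21a, a chemokine with near-identical copies, was at 10.6 CPM in treated replicate 1 and at most 0.0516 CPM in each other library.

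Matrix genes were higher in RH/RQ vehicle hearts and lower in treated hearts, along the same division as the sex-linked genes. Between treated RH/RQ and RH/+ hearts 24 matrix genes were called higher (19 with edgeR, 20 with DESeq2, which called 1 lower). Limma called 0 of the 5 listed sex-linked genes there. This argues against sex alone, with no effect of genotype or treatment. It does not bear on the fall with treatment, nor on how much of the rise goes with sex. A loss of fibroblasts as large as the fall of the matrix genes is argued against by the 14 fibroblast markers outside the matrix list. Their median log2 fold change with treatment was 0.17 against -0.45 for the matrix list, a difference of 0.616 (two-sided permutation p = 7e-05 over genes, which are not independent replicates, 100000 resamples). The 3 markers called lower are matrix genes and so not among the 14. Over all 20 markers the median was 0.11 and the mean -0.05, so a smaller loss is not excluded. With the matrix genes set aside, the test does not cover fibroblasts marked only by those genes. The RH/RQ groups also differed in the sex-linked pattern, so an effect of sex on these markers cannot be separated from one of treatment. Sex behind part or all of the rise or of the fall cannot be told apart from genotype and treatment. The reason is that 0 libraries break the alignment of sex-linked genes with the group.

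Nppa was at 428 and 753 CPM in treated hearts and at most 143 CPM in any vehicle library, a rise of 470 CPM over the mean of the 4 vehicle libraries. Atrial tissue in the treated samples would bring the abundant atrial transcripts Myl4, Myl7 and Sln. Their levels differed from that mean by 0.581, -0.138 and 0.0683 CPM, together 0.11 percent of the rise of Nppa, which argues against it. A rise of Nppa in other heart tissue with treatment is a hypothesis, which may hold but was not tested, and Nppa was also higher than in RH/+ hearts, which share the sex-linked pattern (log2 fold change 2.17).

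Per1, Ddit4 and Tsc22d3, a glucocorticoid target chosen after its values were seen, were higher in treated hearts than in either vehicle group; Tsc22d3 was at 81.2 and 84.8 CPM in RH/+, 82.5 and 71.7 CPM in RH/RQ vehicle and 171 and 157 CPM in treated hearts (limma adjusted p = 1.53e-07 and 1.37e-06 against vehicle RH/RQ and RH/+). Arntl, Dbp, Nr1d1, Nr1d2 and Ciart argue against a difference from RH/+ in time of day at harvest that moves clock genes as much as Per1. Their largest absolute log2 fold change was 0.33, at most 0.59 with 2 standard errors added, against at least 1.23 for Per1 with 2 subtracted. A smaller difference in time is not excluded, as Arntl stood 0.33 (SE 0.13) above RH/+. Between the RH/RQ groups 4 other clock genes were also higher with the reported scaling, so a difference in time between those groups stays open. More glucocorticoid signalling may also be involved. Of 16 tested genes on an added list of responsive genes 8 were higher than in RH/+ and 6 than in vehicle RH/RQ hearts. The camera p, not adjusted over lists, was 3.5e-09 and 9.2e-07 in that order, and 0.04 and 0.063 with an estimated correlation. The last p misses 0.05, and Zbtb16, a further target, was not higher than in RH/+ (log2 fold change -0.42, limma adjusted p = 0.0586). Fkbp5, also a target, was called against neither vehicle group. Its log2 fold change was 0.38 against RH/+ (limma adjusted p = 0.0909) and 0.24 against vehicle RH/RQ (limma adjusted p = 0.414). These values do not tell that explanation apart from others.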
